A study of Mus musculus with 24 samples.

How the data were processed

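Mouse embryonic stem cells of the E14 line were grown in N2B27 medium with the MEK and GSK3 inhibitors and LIF (nESC) or for 3 days with activin A at 20 ng/ml and bFGF at 12 ng/ml (EpiLC), per the labels' protocols. Nuclei were separated over a sucrose buffer, and RNA of chromatin, nucleoplasm, cytoplasm and whole cells was extracted with TRIzol, depleted of ribosomal RNA with Ribo-zero gold, made into libraries with the TruSeq Stranded Total RNA kit and sequenced on a HiSeq system, per the same protocols. The 24 libraries form 8 groups of 3. Grouping followed the labels, which give each library a cell state, a fraction and a replicate number.

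The deposited values are FPKM per gene, made by the authors with TopHat2 and Cuffnorm on mm10 (GRCm38), per the submitters' processing notes. The versions of TopHat2 and Cuffnorm, the annotation, the library normalization setting and the use of strand in counting are not given in the sources used here. There is 1 table per cell state with 12 libraries, normalized on its own, and both hold the same genes, of which 29586 were matched to a symbol by Ensembl ID and 173 were not. FPKM sums per library ran from 432706 to 1980223, so the tables are not scaled to one sum. All per-sample columns were used. No pair of libraries shared more than 1 equal value among genes above 1 FPKM.

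Counts are not in these tables, and depth was read from the steps between low FPKM values. Over 1276 genes of 3000 to 10000 bp of exonic length, 92.5% to 98.8% of low values lay within 10% of a whole multiple of 1 step per library. The steps put 24.2 to 93.3 fragments behind 1 FPKM in a transcript of 2 kb, and 11533 to 13736 genes had at least 1 FPKM. Low values therefore rest on few fragments, most of all in chromatin and cytoplasm. In 15 cases a library was listed at 0 where the other libraries of its group had at least 5 FPKM. The lowest Pearson's r between replicates across genes was 0.966 in nESC chromatin, 0.955 in EpiLC chromatin and 0.988 or more in the other groups, and genes are not independent replicates.

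Fractions were compared within a cell state with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, two-sided) on log2(FPKM + 0.5). Genes with a mean of at least 1 FPKM over the 12 libraries of a table were tested, with its 4 kinds of library fitted together. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. The comparisons were chromatin with cytoplasm, nucleoplasm with cytoplasm, chromatin with nucleoplasm and cytoplasm with total RNA in each state, and the difference of chromatin with cytoplasm between the states as an interaction over 12 libraries, each centred on its median. Levels of the states were given as means and SD of FPKM with no test. Groups of 3 libraries that do not overlap arise by chance for 10% of genes.

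There were 24 gene lists: nuclear noncoding RNAs, spliced noncoding RNAs described as exported, ribosomal proteins, the mitochondrial genome, nuclear respiratory chain genes, the proteasome, the secretory pathway, replication histones, immediate early genes, genes with detained introns, long genes, chromatin regulators, naive, formative and core pluripotency genes, MEK and GSK3 response genes, markers of primitive endoderm, trophectoderm, mesoderm and neural cells, 2-cell-like cells and fibroblasts or feeders, housekeeping genes, zinc finger genes with Zfp names and genes with clone-type names. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Only the calls on clone-named genes in 3 comparisons and on proteasome genes in 1 held with the estimated correlation.

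Genes to be named were set by a rule: the called genes with the largest folds in each direction whose groups (for the interaction, the ranges of the fraction differences of each state) did not overlap and whose higher mean was at least 5 FPKM, with clone-type names and names of small RNAs left out, up to 4 members of each list by absolute fold, and a fixed set of marker genes. The rule gave 88 to 103 genes per comparison. The text prints 15 to 41 of them per comparison, and this part was picked among the rule's genes with their values in view. The comparisons, tests, thresholds, lists, naming rule and most alternatives were fixed before the data were examined.

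Alternatives were pseudocounts of 0.1 and 1, no filter and a mean of at least 5 FPKM, each library centred on its median, each library scaled to one sum, no centring for the interaction, no trend, only the 2 fractions compared, the replicate number as a block and each library left out in turn. Chosen after seeing the data were isolated zeros treated as missing, both EpiLC libraries numbered 3 left out, a correction of each library for exonic length and GC content with a spline of 5 degrees of freedom, and the sum scaling of lists. The fits were tested on simulated data with 50 changed genes per fold size, drawn as independent normal values around 1 mean per gene. At a fold of 2.5, 96% were recovered in nESC chromatin against cytoplasm (12592 genes), 98% in EpiLC (12834 genes) and 80% in the interaction (11704 genes), and at a fold of 1.5 0%, 2% and 2%, since the threshold asks for a fold of 2. Tables were prepared and drawn with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.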

Results

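RNA sequencing was performed on mouse embryonic stem cells of the E14 line in 2 cell states. Naive embryonic stem cells (nESC) were kept with inhibitors of MEK and GSK3 and with LIF, and epiblast-like cells (EpiLC) were collected on day 3 of culture with activin A and bFGF. From each state, RNA of a chromatin, a nucleoplasm and a cytoplasm fraction and RNA of whole cells (total) was sequenced in 3 libraries each, which gives 8 groups and 24 libraries. Each cell state has its own table of genes in FPKM, with a symbol for 29586 of them and none for 173. The 2 tables were normalized separately. Fractions were therefore compared within a state, and levels of the 2 states were set side by side with no test. The FPKM steps of low genes put 30.9 to 48.0 fragments behind 1 FPKM in a transcript of 2 kb in the chromatin libraries and 24.2 to 44.3 in the cytoplasm libraries. The ranges were 68.0 to 93.3 in nucleoplasm and 63.5 to 83.9 in total RNA. The labels do not say that the replicates are separate cultures, so the p-values below measure only the spread between these samples, which may be technical. Across genes, mean log2 values of chromatin and cytoplasm had a Pearson's r of 0.633 in nESC and 0.708 in EpiLC, and genes are not independent replicates.

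In total RNA the naive pluripotency genes stood at higher FPKM in nESC and the formative epiblast genes at higher FPKM in EpiLC. Nanog, a core transcription factor of naive cells (chromosome 6, 122707489 to 122714633, mm10), had 277 ± 2.92 FPKM (SD, n = 3) in nESC and 14.2 ± 0.688 in EpiLC. Zfp42, the naive marker also called Rex1, had 391 ± 19.5 and 12.3 ± 0.454. Tcl1 had 155 ± 5.36 and 1.29 ± 0.313, Esrrb 100 ± 7.01 and 5.61 ± 0.408, and Klf4 12.8 ± 1.13 and 1.45 ± 0.0377. Fgf5, a growth factor gene of the early postimplantation epiblast (chromosome 5, 98254184 to 98277030), had 0.0553 ± 0.0178 in nESC and 54.2 ± 1.45 in EpiLC. Pou3f1 had 0.0715 ± 0.0284 and 32.3 ± 0.376, and Otx2 3.88 ± 0.117 and 86.5 ± 4.43. The de novo DNA methyltransferase genes Dnmt3b and Dnmt3a had 22.2 ± 0.144 and 778 ± 20.9, and 5.04 ± 0.574 and 158 ± 3.21. Of 27 naive genes with at least 1 FPKM in either state, 26 were at least 2-fold higher in nESC, with a median log2 difference of -3.69, EpiLC minus nESC. Of 29 formative genes, 24 were at least 2-fold higher in EpiLC, with a median of 3.58. These level differences have no test because the tables were normalized separately. The median over 11704 genes was -0.01 as deposited and 0.2 after scaling each library to one sum.

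Other groups moved less uniformly. Pou5f1, the gene of OCT4, had 994 ± 31.1 FPKM in nESC and 867 ± 16 in EpiLC, while Sox2 had 172 ± 6.76 and 32.1 ± 0.398. Of 16 core pluripotency genes 7 were at least 2-fold higher in EpiLC and 1 in nESC. Among 21 genes that respond to MEK and GSK3 signalling, 10 were at least 2-fold higher in EpiLC, with the phosphatase gene Dusp4 at 0.572 ± 0.0333 and 39.6 ± 1.57. In nESC 5 were higher, with the Wnt target Notum at 50.8 ± 2.35 and 0.74 ± 0.0645. Of the markers of other cell types, Apoe of the primitive endoderm list had 1250 ± 60.3 and 285 ± 2.36, Eif1a of the 2-cell-like list 192 ± 9.59 and 95 ± 2.19, and T and Nes of the mesoderm and neural list 12.4 ± 0.861 and 0.209 ± 0.186, and 9.65 ± 0.329 and 18.8 ± 0.899. Zscan4c and Gm5662 of the 2-cell-like list were far lower than Eif1a, at 5.96 ± 0.493 and 2.09 ± 0.323, and 2.67 ± 0.307 and 0.346 ± 0.15. Of 16 primitive endoderm genes only 2 had at least 1 FPKM in either state, and both were at least 2-fold higher in nESC. In the 2-cell-like list of 18 genes, 8 reached that level and 6 of them were at least 2-fold higher in nESC. After scaling each library to one sum, Eif1a (-0.79) and Zscan4f (-0.91) fell short of 2-fold. In EpiLC 5 of 8 fibroblast and feeder genes at that level were higher (Thy1, 0.868 ± 0.645 and 7.32 ± 0.616). The trophectoderm list and the mesoderm and neural list, with 4 and 5 genes at that level, were split, with 2 genes higher in each state.

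**Figure D1:**
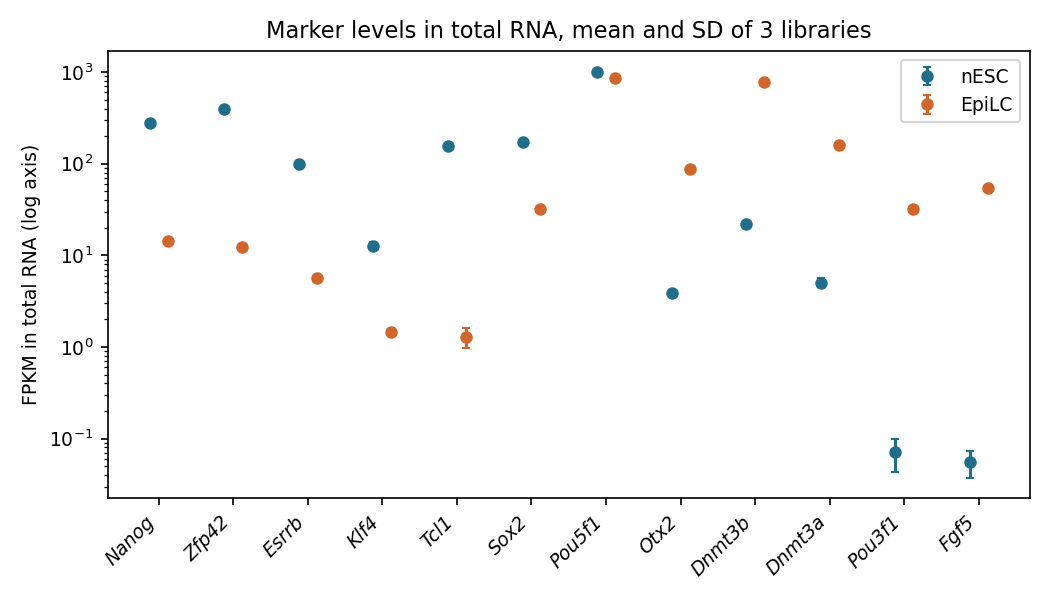
Marker genes (x axis) and their level in total RNA in FPKM on a log axis (y axis), as mean and SD of 3 libraries per cell state. Nanog stood at 277 FPKM in nESC and 14.2 in EpiLC and Fgf5 at 0.0553 and 54.2, while Pou5f1 stood at 994 and 867; the tables were normalized separately and the levels have no test.

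Chromatin and cytoplasm of nESC were compared to find which transcripts stay at the template and which are exported. Messages of the translation and energy machinery were higher in cytoplasm, and nuclear noncoding RNAs, genes with detained introns and chromatin regulators were higher in chromatin. Rplp1, a ribosomal stalk protein gene (ENSMUSG00000007892, chromosome 9, 61913284 to 61914542), had 769 ± 148 FPKM in chromatin and 26550 ± 2220 in cytoplasm (SD, n = 3), a log2 fold of -5.12 (SE 0.13, adjusted p = 1.1e-12). The imprinted noncoding RNA Meg3 (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726) had 354 ± 28.6 and 13.5 ± 1.11, a log2 fold of 4.67 (SE 0.09, adjusted p = 2.71e-13). Rbm25, a splicing factor gene, had 388 ± 30.9 and 11.4 ± 1.42, a log2 fold of 5.03 (SE 0.09, adjusted p = 2.08e-13). Of 12592 genes tested with limma, 7745 were called, 4003 higher and 3742 lower in chromatin.

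Clone-type names left out, the largest folds toward nESC chromatin included Hsp90aa1, the HSP90 alpha chaperone gene, at 8.20 (SE 0.17, adjusted p = 3.51e-13), Macf1, a cytoskeletal linker gene, at 6.50, the nuclear pore gene Ranbp2 at 6.37, Tmem72 at 6.23 and the proliferation marker Mki67 at 6.23. Hsp90aa1 had 696 ± 131 FPKM in chromatin and 1.9 ± 0.67 in cytoplasm, while nESC total RNA held 4281 ± 166 and EpiLC cytoplasm 416 ± 225. Its fold cannot be read as a distribution of RNA while the low value in nESC cytoplasm is unexplained. Toward cytoplasm they included Smim22 at -5.73 (SE 0.28, adjusted p = 3.09e-10) and the histone H4 genes Hist1h4j at -5.66 and Hist1h4m at -5.50. Near-identical copies make the assignment of reads to single H4 genes uncertain. The same holds for the zinc finger genes Zfp600, at 5.88 (SE 0.11, adjusted p = 2.08e-13), and Zfp980, at 5.85, which lie in a cluster of similar genes on chromosome 4. Malat1, a nuclear noncoding RNA, had 4864 ± 531 FPKM in chromatin and 173 ± 7.92 in cytoplasm, a log2 fold of 4.81 that was not called (SE 2.44, adjusted p = 0.0809). It is listed at 0 in nESC nucleoplasm replicate 3 beside 3810 and 3590. With such isolated zeros treated as missing it was called, with an adjusted p of 5.3e-13.

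By group, 77 of 78 ribosomal protein genes were lower in nESC chromatin and 1 was higher, with a median log2 fold of -3.81 (camera adjusted p = 2.32e-19). Adjusted p was 0.24 with an estimated correlation, and Rps14 was at -4.98. All 60 replication histone genes were lower (median -4.12, 1.83e-18), as were 67 of 70 nuclear respiratory chain genes (-2.92, 8.41e-17), 26 of 31 proteasome genes (-2.02, 1.36e-09) and 16 of 19 housekeeping genes (-2.35, 4.21e-05). Adjusted p was 0.161, 0.19, 0.132 and 0.151 in that order with an estimated correlation. Atp5e, an ATP synthase subunit gene, was at -4.87, Psmb5 at -3.69, Ppia, the cyclophilin A gene, at -3.51, Gapdh at -2.57 and Actb at -2.39. Higher in chromatin were 32 of 41 genes with detained introns (median 2.76, 5.96e-10), 32 of 51 chromatin regulators (1.54, 4.21e-05), 14 of 17 nuclear noncoding RNAs (3.47, 4.21e-05), 16 of 23 long genes (1.56, 0.00601) and 212 of 334 zinc finger genes (1.57, 2.67e-10). Adjusted p was 0.151, 0.132, 0.0846, 0.132 and 0.151 in that order with an estimated correlation. Examples were the cyclin gene Ccnl1 at 4.65, the chromatin remodeller Atrx at 5.37, the DNA demethylase gene Tet1 at 4.17, Kcnq1ot1 at 4.60, Neat1 at 3.47 and Diaph2 at 4.52. Genes with clone-type names were called higher in 757 and lower in 251 of 1326 cases (median 1.43, 2.8e-06). Adjusted p was 0.0327 with an estimated correlation. For every list in this comparison the counts adjusted over the list alone were equal to those over all genes.

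No shift was called by camera for the other lists with at least 5 tested genes. Spliced noncoding RNAs described as exported had 7 of 12 higher in nESC chromatin and 2 lower (median 1.84, adjusted p = 0.0828). Among them were the snoRNA host Gas5 at 4.57 (SE 0.10, adjusted p = 3.72e-13) and Dancr at 4.02. The mitochondrial genome had 4 of 13 higher and 4 lower (median 0.55, mean -0.04, adjusted p = 0.954), with mt-Nd4 at 2.19 and mt-Co3 at -3.19. The secretory pathway had 13 of 53 higher and 16 lower (median -0.01, or 1.91 after scaling each library to one sum, adjusted p = 0.954), with the transferrin receptor gene Tfrc at 3.54 and the translocon gene Sec61b at -3.30. Immediate early genes had 5 of 21 higher and 7 lower (median -0.72, or 1.16 after that scaling, adjusted p = 0.387), with Fos at 3.88 and Fosb at 3.53. Naive genes had 5 of 27 higher and 8 lower (median -0.25, or 1.71 after that scaling, adjusted p = 0.387). Formative genes had 7 of 23 higher and 6 lower (median -0.13, mean -0.01, or 1.76 after that scaling, adjusted p = 0.978, camera direction upward). Core genes had 4 of 16 higher and 4 lower (median 0.10, adjusted p = 0.982). MEK and GSK3 response genes had 6 of 17 higher and 1 lower (median 0.25, adjusted p = 0.356). Of the 2-cell-like genes 4 of 6 were higher and 1 lower (median 2.19, adjusted p = 0.387), with Zscan4c, one of several near-identical copies, at 3.05. Pou5f1 was at -3.88 (SE 0.11, adjusted p = 2.83e-12), the telomere protein gene Rif1 at 5.04 and Dppa5a at -4.03, while Klf4 had 63.4 ± 4.43 FPKM in chromatin and 15.9 ± 2.9 in cytoplasm. All 3 primitive endoderm genes (median -2.04) and all 3 trophectoderm genes (median -1.4, or 0.04 after that scaling) tested were lower in chromatin. The mesoderm and neural list had 2 higher and 1 lower of 4, and the only fibroblast gene tested was not called.

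The scaling of the libraries set much of the balance in nESC. The median of all genes was 0.041 as deposited, -0.217 after centring and 1.845 after scaling each library to one sum. With that scaling 9161 genes were called, 8410 higher and 751 lower. The same scaling turned Nanog from -1.93 (SE 0.08, adjusted p = 3.87e-11) to 0.03 and Sox2, not called at -0.51, to 1.45. It ended the calls on Gapdh and Actb at -0.60 and -0.42. Centring called 3431 higher and 4374 lower, and a filter at a mean of at least 5 FPKM 2511 higher and 3160 lower. After correction of each library for exonic length and GC content 6228 genes were called, 2505 higher and 3723 lower, with Kcnq1ot1 at -0.76, Neat1 at 0.61 and mt-Nd4 at 0.48. The libraries of the 2 groups did not overlap for 85.9% of genes, where chance gives 10%.

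In EpiLC the same comparison again placed nuclear noncoding RNAs and zinc finger genes toward chromatin and ribosomal, histone and respiratory chain messages toward cytoplasm. Malat1 had 4545 ± 993 FPKM in chromatin and 221 ± 82.7 in cytoplasm (SD, n = 3), a log2 fold of 4.40 (SE 0.22, adjusted p = 1.7e-09). Rplp1 had 779 ± 493 and 16310 ± 1190, a log2 fold of -4.56 (SE 0.30, adjusted p = 1.66e-08). Clone-type names left out, the largest folds included those of Zfp979 at 5.33, Rex2 at 5.30, Zfp970 at 5.28, Zfp980 at 5.19 and Zfp600 at 5.05. These are members of groups of similar zinc finger genes whose reads cannot be assigned with certainty. In the other direction were Hist1h4b at -5.23, Ndufc1, a complex I subunit gene, at -4.97 (SE 0.48, adjusted p = 5.88e-07), Hist1h4j at -4.93, Hist1h2ad at -4.69 and Rps12-ps3 at -4.93. The last name is that of a ribosomal pseudogene, and its reads may belong to its parent. Of 12834 genes tested, 7386 were called, 3737 higher and 3649 lower in chromatin.

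All 78 ribosomal protein genes were lower in EpiLC chromatin (median -3.28, camera adjusted p = 2.98e-16), as were 60 of 61 replication histone genes (-3.34, 2.45e-16), 67 of 70 respiratory chain genes (-2.77, 7.47e-13), 29 of 31 proteasome genes (-2.37, 1.76e-10) and 16 of 19 housekeeping genes (-2.59, 1.02e-05). Adjusted p was 0.419, 0.374, 0.419, 0.119 and 0.168 in that order with an estimated correlation. Atp5e was at -4.54, Psmb5 at -3.75, Ppia at -3.70, Actb at -2.96 and Gapdh at -2.59. Higher were 15 of 18 nuclear noncoding RNAs (2.54, 5.91e-05), 25 of 41 genes with detained introns (1.56, 5.91e-05), 18 of 23 long genes (1.95, 0.000118), 27 of 53 chromatin regulators (1.11, 0.00151) and 213 of 342 zinc finger genes (1.65, 2.9e-11). Adjusted p was 0.238, 0.419, 0.313, 0.633 and 0.374 in that order with an estimated correlation. The 1 nuclear noncoding RNA called lower was Gm26917, a transcript over a ribosomal RNA repeat, listed at 0 in all chromatin libraries and at 2134 ± 387 in cytoplasm. Examples of the other direction were Kcnq1ot1 at 4.08, Meg3 at 3.53, Gas5 at 2.98 and Neat1 at 1.78. Others were Rbm25 at 3.86, Ccnl1 at 3.82, Diaph2 at 3.85, the remodeller gene Chd9 at 4.17, Atrx at 3.75 and Tet1 at 3.72. Clone-type names were called higher in 767 and lower in 192 of 1321 cases (1.47, 2.31e-09). Adjusted p was 0.119 with an estimated correlation.

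Formative genes had 12 of 29 lower in EpiLC chromatin and 5 higher (median -0.35, or 1.47 after scaling each library to one sum, adjusted p = 0.286). Lin28b, an inhibitor of let-7 processing, was at 3.60 (SE 0.23, adjusted p = 1.21e-08), while the keratin gene Krt18 was at -2.86, Utf1 at -2.43 and Dnmt3l, a cofactor of the de novo methyltransferases, at -2.35. Fgf5 was at -1.03 (SE 0.10, adjusted p = 4.02e-07) and lost its call without chromatin replicate 2 (-0.97). Dnmt3b was at -1.14, Nanog at -1.40, Dppa5a at -3.48 and Pou5f1 at -3.47. Sox2 at -0.90 (-1.10 and called after centring) and Otx2 at -0.29 were not called. The mitochondrial gene mt-Nd6 was at 2.53 (SE 0.40, adjusted p = 7.12e-05). For mt-Co1 the fold of 0.98 was not called (SE 0.45, adjusted p = 0.0571). It had 1.5 and a call without chromatin replicate 2 and 0.29 without chromatin replicate 3.

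Libraries numbered 3 of EpiLC chromatin and cytoplasm stood apart from their groups. The chromatin libraries had 1894, 1133 and 6077 FPKM of mt-Co1, and the endoplasmic reticulum chaperone gene Hsp90b1 had 38.0, 35.2 and 85.0 in the cytoplasm libraries. Without both of them 7717 genes were called in this comparison, 5439 between nucleoplasm and cytoplasm, 4555 between chromatin and nucleoplasm and 4418 between cytoplasm and total. After scaling to one sum 9076 genes were called, 8410 higher and 666 lower. The median of all genes moved from -0.001 to 1.695 (-0.20 after centring, with 3293 genes higher and 4183 lower). Scaling to one sum turned Nanog (0.36), Sox2 (0.93), Otx2 (1.54), Fgf5 (0.78) and Dnmt3b (0.70) toward chromatin and ended the calls on Gapdh (-0.75), Utf1 (-0.60) and Dnmt3l (-0.52). With a mean of at least 5 FPKM 2253 were higher and 3198 lower. After the length and GC correction 5883 genes were called, 2371 higher and 3512 lower, with Neat1 at -0.47, Kcnq1ot1 at 0.00, Atrx at 0.82 and mt-Nd6 at 0.47. The groups did not overlap for 82.7% of genes, where chance gives 10%.

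**Figure D2:**
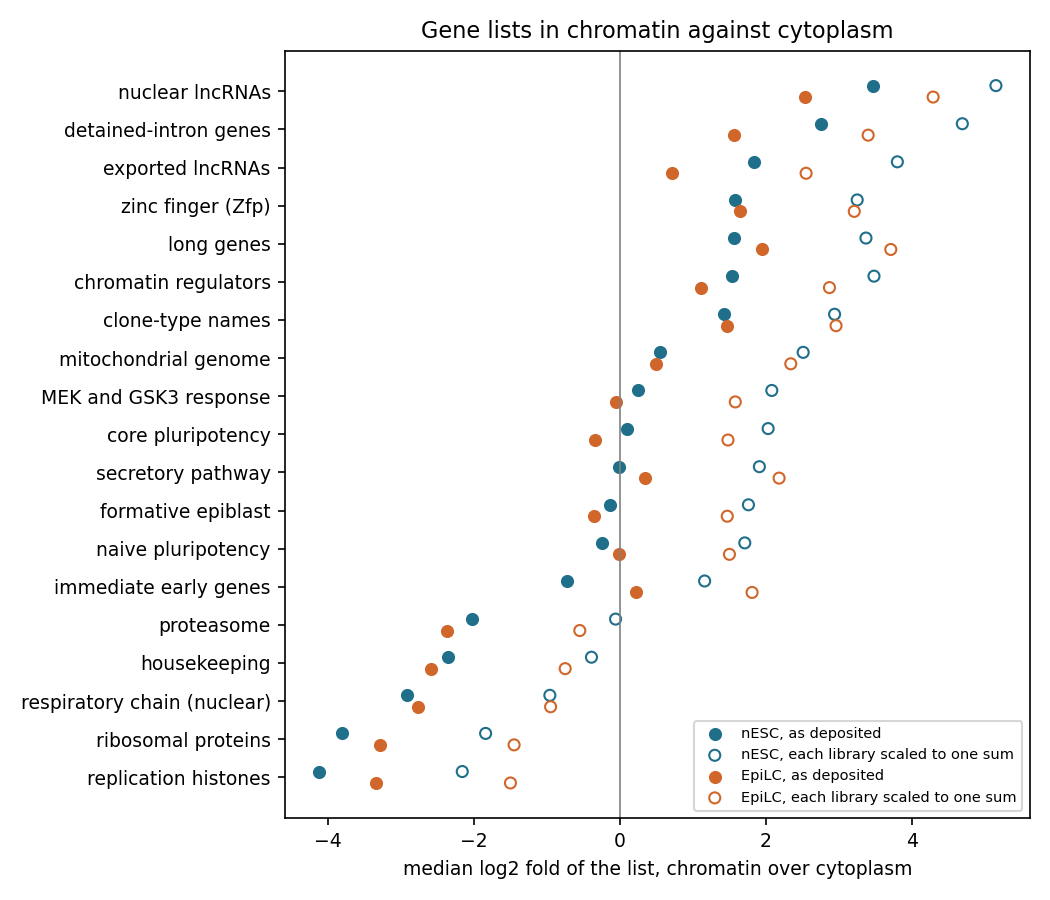
Median log2 fold of chromatin over cytoplasm (x axis) for 19 gene lists (y axis) in nESC and EpiLC, with filled points for values as deposited and open points after scaling each library to one sum. Ribosomal proteins lay at -3.81 in nESC and -3.28 in EpiLC and stayed below 0 under both scalings, nuclear noncoding RNAs lay at 3.47 and 2.54, and the naive, formative, core and immediate early lists, between -0.72 and 0.22 as deposited, lay above 1 after scaling.

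Across the 11704 genes tested in both states, 2976 were called higher in chromatin in both, where independent lists would share 1042, and 2954 were lower in both, where they would share 1055. Opposite calls were found for 19 genes. The log2 folds of the states had a Pearson's r of 0.941 across genes, which are not independent replicates, and the slope of EpiLC on nESC was 0.847.

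Nucleoplasm and cytoplasm were compared in each state for transcripts that had left chromatin without being exported. Messages of secretory pathway proteins and of the mitochondrial genome were higher in nucleoplasm, and histone and ribosomal protein messages were higher in cytoplasm. Mitochondrial messages are not made in the nucleus, so their folds cannot be read as RNA that was not exported. In nESC, Hsp90b1 (ENSMUSG00000020048, chromosome 10, 86690209 to 86705509) had 498 ± 24.2 FPKM in nucleoplasm and 34.6 ± 4.62 in cytoplasm (SD, n = 3), a log2 fold of 3.84 (SE 0.10, adjusted p = 1.79e-11). In EpiLC it had 848 ± 146 and 52.7 ± 28, a log2 fold of 4.10 (SE 0.32, adjusted p = 2.23e-07). The lysosomal gene Lamp2 was at 3.28 and 3.15 and Tfrc at 3.07 and 3.39 in nESC and EpiLC. In the secretory pathway list 31 of 53 genes in nESC (median 1.18, camera adjusted p = 9.92e-10) and 34 of 53 in EpiLC (1.35, 3.67e-08) were higher in nucleoplasm. Adjusted p was 0.16 and 0.5 in that order with an estimated correlation.

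Of 13 genes of the mitochondrial genome, 11 were higher in nESC nucleoplasm (median 1.69, camera adjusted p = 5.93e-05) and all 13 in EpiLC nucleoplasm (2.89, 0.000158). Adjusted p was 0.16 and 0.5 in that order with an estimated correlation. The cytochrome oxidase gene mt-Co1 was at 2.30 (SE 0.20, adjusted p = 2.05e-07) in nESC and 3.34 (SE 0.45, adjusted p = 2.06e-05) in EpiLC, mt-Atp8 at 3.37 in nESC and mt-Nd6 at 4.74 in EpiLC. All 60 replication histone genes in nESC (median -3.30, 4.89e-22) and 59 of 61 in EpiLC (-2.40, 6.23e-18) were lower in nucleoplasm, with Hist1h4j at -3.96 and -3.39. Others were Hist1h3c at -3.96 and Hist2h2aa1 at -3.87 in nESC, and Hist1h4m at -3.2 and Hist1h4i at -3.18 in EpiLC, all from families of near-identical genes. Adjusted p was 0.16 and 0.455 in that order with an estimated correlation. Ribosomal protein genes were lower in nucleoplasm in 69 of 78 cases in nESC (-1.66, 1.24e-16) and 71 of 78 in EpiLC (-1.46, 2.45e-11), with Rplp1 at -2.71 in nESC and Rps2 at -2.59 in EpiLC. Adjusted p was 0.271 and 0.5 in that order with an estimated correlation. Respiratory chain genes (medians -0.72 and -0.91) and proteasome genes (-0.96 and -0.73) were also lower as deposited but turned to 0.55 and 0.13, and to 0.30 and 0.30, after scaling each library to one sum, as housekeeping genes did in EpiLC (-0.83 to 0.21).

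Genes with detained introns were higher in nucleoplasm in 26 of 41 cases in nESC (median 1.72, camera adjusted p = 1.38e-08) and 20 of 41 in EpiLC (0.91, 1.86e-05), with the kinase gene Prpf4b at 3.47 in nESC and Rbm25 at 3.25 in EpiLC. Adjusted p was 0.16 and 0.455 in that order with an estimated correlation. Chromatin regulators were higher in 25 of 51 cases (0.90, 3.68e-06) and 28 of 53 cases (1.14, 2.06e-07), with Tet1 at 3.86 in nESC and the methyltransferase gene Setd2 at 3.91 in EpiLC. Adjusted p was 0.16 and 0.455 in that order with an estimated correlation. Nuclear noncoding RNAs passed camera in nESC (0.88, 0.00472) and not in EpiLC (0.34, adjusted p = 0.187). Adjusted p was 0.16 and 0.563 in that order with an estimated correlation, and the difference between the states was not tested for these fractions. Meg3 was at 3.61, Tug1 at 2.76 and Firre at 2.74 in nESC, and Malat1 at 2.95 and Tug1 at 2.28 in EpiLC. In EpiLC Lin28b was at 3.32 and Enpp2, the autotaxin gene, at 3.09. Other clone-type names left out, the largest folds toward nucleoplasm included Hsp90aa1 at 10.29, the repeat transcript Gm26917 at 7.60, Rrp1 at 6.31 and Rrp15 at 5.39 in nESC. These genes had 1.9 ± 0.67, 2.368 ± 0.959, 0.536 ± 0.051 and 0.659 ± 0.29 FPKM in nESC cytoplasm. Their folds rest on these unexplained low values and cannot be read as RNA that was not exported. In EpiLC they were the similar zinc finger genes Zfp980 at 5.30, Rex2 at 4.94 and Zfp988 at 4.94 (5.34 in nESC).

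In all, 5028 genes were called in nESC, 2577 higher and 2451 lower in nucleoplasm, and 5035 in EpiLC, 2579 higher and 2456 lower. Median folds of all genes were -0.082 and -0.15. Scaling to one sum moved them to 0.973 and 0.722 and called 6144 higher and 128 lower, and 5172 higher and 221 lower. Centring moved them to -0.307 and -0.33 and called 2064 higher and 3369 lower, and 2196 higher and 3266 lower. With a mean of at least 5 FPKM 1990 were higher and 2090 lower, and 2022 higher and 2052 lower. With the length and GC correction 3246 (1316 higher, 1930 lower) and 3174 (1285 higher, 1889 lower) genes were called, mt-Atp8 was at 0.80 and Tug1 at 0.45 in nESC, and Tug1 turned to -0.12 in EpiLC. The groups did not overlap for 84.9% and 81.2% of genes, where chance gives 10%.

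Between chromatin and nucleoplasm, noncoding RNAs and clone-named genes were higher in chromatin and messages of the ribosome, respiratory chain and proteasome were higher in nucleoplasm. The antisense transcript Lrrc75aos2 (ENSMUSG00000085762, chromosome 11, 62605766 to 62607748) had 38.6 ± 8.3 FPKM in nESC chromatin and 0.530 ± 0.0901 in nucleoplasm (SD, n = 3), a log2 fold of 5.23 (SE 0.22, adjusted p = 4.4e-10). In EpiLC it had 42.7 ± 0.457 and 1.52 ± 0.104, a log2 fold of 4.42 (SE 0.11, adjusted p = 1.73e-10). The kit marks strand, and whether the counting used it is not given in the sources used here. Gpr151, a receptor gene, was at 4.84 and 4.27, Arsb, a sulfatase gene, at 5.09 in nESC, and Fosb at 3.57 in nESC and 4.24 in EpiLC, where Fos was at 2.95. In the other direction, clone-type names left out, stood Lst1 at -3.95, the fatty acid binding protein gene Fabp3 at -3.76 and S100a1 at -3.64 in nESC. In EpiLC they were mt-Atp8 at -3.03, mt-Co2 at -2.94 and Tbcb, a tubulin folding cofactor gene, at -2.84.

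Nuclear noncoding RNAs were higher in chromatin in 12 of 17 cases in nESC (median 2.02, camera adjusted p = 5.89e-06) and 15 of 18 in EpiLC (2.00, 1.55e-06), with Kcnq1ot1 at 3.85 and 3.17 and Mirg at 3.69 and 3.13. The 1 called lower in each state was Gm26917, listed at 0 in all 6 chromatin libraries and at 540.5 ± 61.5 FPKM in nESC and 1139 ± 79.4 in EpiLC nucleoplasm. For the list, adjusted p was 0.051 and 0.0969 with an estimated correlation, and Meg3 was at 1.96 in EpiLC. Spliced noncoding RNAs described as exported were higher in 8 of 12 (1.59, 0.00316) and 9 of 13 (1.45, 3.67e-05), with Gas5 at 3.23 and 2.98. Adjusted p was 0.183 and 0.131 in that order with an estimated correlation. Clone-named genes were higher in 634 and lower in 124 of 1326 in nESC, and higher in 728 and lower in 82 of 1321 in EpiLC, and their calls held with an estimated correlation (adjusted p = 0.00659 and 0.0312). Ribosomal protein genes were lower in 70 of 78 (median -2.11, 1.55e-22) and 72 of 78 (-1.79, 5.72e-15), Rps29 being at -3.2 in nESC. Adjusted p was 0.168 and 0.398 in that order with an estimated correlation. Respiratory chain genes were lower in 64 of 70 in nESC and 69 of 70 in EpiLC (adjusted p = 0.132 and 0.398 with an estimated correlation). Proteasome genes were lower in 20 of 31 in nESC and 30 of 31 in EpiLC, the latter with an adjusted p of 0.0463 with an estimated correlation, and Psmb5 was at -2.61 in EpiLC. In the secretory pathway 36 of 53 and 33 of 53 were lower, and mt-Co1 was at -3.30 in nESC.

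Ccnl1 was at 2.24 in nESC and 1.94 in EpiLC, and the acetyltransferase gene Ep300 at 2.44 in nESC. Of 16 core pluripotency genes, 3 were lower and 1 was higher in nESC chromatin (median -0.49, or 0.21 after scaling to one sum, camera adjusted p = 0.239). In EpiLC 4 were lower (-0.74, or 0.06 after that scaling, 0.00114), with an adjusted p of 0.187 with an estimated correlation. Pou5f1 was at -1.95 and -1.70 and the Nodal coreceptor gene Tdgf1 at -2.51 in nESC. The higher gene was Rif1 at 1.03, a call lost after centring (0.99), with the length and GC correction (0.22) and without nESC chromatin replicate 2 (1.00) or 3 (0.97) or nucleoplasm replicate 2 (0.98). In EpiLC Dnmt3l was at -2.01 and Dnmt3b at -1.19. T, the brachyury gene, was at 3.46 (SE 0.20, adjusted p = 7.41e-09) and Sp5 at 3.43 in nESC, both Wnt targets. A total of 4374 genes in nESC, 2195 higher and 2179 lower, and 4199 in EpiLC, 2058 higher and 2141 lower, were called. Scaling to one sum moved the median of all genes from 0.018 to 0.692 and from -0.067 to 0.695, with 4857 higher and 919 lower, and 4840 higher and 507 lower. It ended the EpiLC calls on Pou5f1 (-0.90) and Dnmt3b (-0.38). The filter turned the balance too. With no filter 3299 were higher and 2229 lower in nESC and 3251 and 2147 in EpiLC, and with a mean of at least 5 FPKM 1101 and 1907 in nESC and 832 and 2005 in EpiLC. In nESC more genes were lower than higher also after centring (2100 higher, 2263 lower), with the length and GC correction (1890, 2057), without chromatin replicate 1 and with a pseudocount of 0.1 (2379, 2382) or 1 (1969, 2020). The groups did not overlap for 77.4% and 72.2% of genes, where chance gives 10%.

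Cytoplasm was compared with total RNA to see how the isolated fraction differs from RNA of whole cells. Total RNA did not lie between the fractions for every gene. In nESC, Jun had means of 4.17, 3.9 and 5.08 FPKM in chromatin, nucleoplasm and cytoplasm against 0.459 in total RNA. Fos was also lower in total RNA than in each fraction in nESC, and higher than in each in EpiLC. Folds against total RNA therefore need not reflect distribution alone, and the reason was not tested. As deposited, histone and ribosomal protein messages were higher in cytoplasm in both states. In nESC, Hist1h4n was at 2.92 (SE 0.14, adjusted p = 2.07e-09). The ribosomal gene Rpl28 (ENSMUSG00000030432, chromosome 7, 4792874 to 4795066) had 4053 ± 44.4 FPKM in cytoplasm and 1080 ± 76 in total RNA (SD, n = 3), a log2 fold of 1.91 (SE 0.11, adjusted p = 9.25e-09). In EpiLC, Hist1h3c was at 2.52 and Rpl28 at 1.85. Replication histones were higher in 59 of 60 and 59 of 61 cases (medians 2.22 and 1.92, camera adjusted p = 3.07e-19 and 1.67e-17), and ribosomal protein genes in 46 and 64 of 78 (1.07 and 1.20, 1.82e-12 and 1.56e-10). Adjusted p was 0.189, 0.316, 0.384 and 0.502 in that order with an estimated correlation. Rpl28, among the largest upward ribosomal folds in both states, fell to 0.94 and 0.85 after scaling each library to one sum. The ribosomal result therefore depends on the scaling, while Hist1h3c stayed at 1.52 in EpiLC.

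Lower in cytoplasm were genes with detained introns, in 28 and 19 of 41 cases (medians -1.58 and -0.92, camera adjusted p = 5.2e-11 and 1.65e-06), with Luc7l3 at -3.89 in nESC and Rbm25 at -3.48 and -3.15. Adjusted p was 0.179 and 0.316 in that order with an estimated correlation. Zinc finger genes were lower in 185 of 334 and 169 of 342 cases, with Zfp970 at -4.72 and -3.93 and Zfp980 at -4.19 in EpiLC. In nESC, other clone-type names left out, the largest folds included Hsp90aa1 at -10.84 (SE 0.17, adjusted p = 5.51e-13), Gm26917 at -10.77 (SE 0.21, adjusted p = 2.32e-12), Rrp1 at -6.76 and Rrp15 at -6.54 downward. These 4 rest on the same low values in nESC cytoplasm and cannot be read as a distribution of RNA. Upward they were Cox8b at 3.76, the ubiquitin-like activating enzyme gene Uba7 at 3.57 and the protocadherin gene Pcdhgc4 at 3.52. Rif1 was at -4.09 and Tfrc at -3.63. In EpiLC the neuropeptide gene Trh was at 2.63 (SE 0.34, adjusted p = 1.93e-05). Psme2b at 2.61, with 10.1 ± 14.7 FPKM in cytoplasm, fell to 1.33 without cytoplasm replicate 1. The immediate early genes Fosb, Fos and Egr1 were at -3.98, -3.73 and -2.87 in EpiLC, mt-Nd6 at -3.65 and Hsp90b1 at -2.84. Pou5f1 was at 1.15 in nESC and 1.14 in EpiLC, Gapdh at 1.36 and 1.30, Esrrb at 1.45 and 2.5, and Zfp42 at -1.15 in nESC.

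Counts of called genes were 4453 in nESC, 2012 higher and 2441 lower in cytoplasm, and 3890 in EpiLC, 1630 higher and 2260 lower. Scaling to one sum moved the median of all genes from 0.114 to -0.714 and from 0.163 to -0.721. It called 222 higher and 4965 lower, and 47 higher and 4918 lower. Centring moved the medians to 0.276 and 0.271 and called 2732 higher and 2069 lower in nESC and 2174 higher and 2019 lower in EpiLC. The sum scaling turned the medians of the proteasome list (to -0.63 and -0.27), of the nESC respiratory chain list (0.80 to -0.16) and of the nESC housekeeping list (0.61 to -0.35). It ended the calls on Pou5f1 (0.19 and 0.14), Gapdh (0.40 and 0.30), Rpl28 (0.94 and 0.85) and nESC Esrrb (0.48). With the length and GC correction 2517 and 2032 genes were called, 1424 higher and 1093 lower in nESC. Pou5f1 was at 0.24 and 0.38, EpiLC Gapdh at 0.91 and Zfp42 at -0.89 (-0.99 after centring). The groups did not overlap for 84.1% and 82.2% of genes, where chance gives 10%.

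Whether the distribution between chromatin and cytoplasm changed from nESC to EpiLC was tested as an interaction over the 12 chromatin and cytoplasm libraries, each centred on its median. A positive value means a larger chromatin share in EpiLC, relative to the median gene. Across genes the slope of EpiLC folds on nESC folds was 0.847. A value opposite in sign to the nESC fold may therefore reflect a weaker separation of the fractions in EpiLC, which was not tested. Of 11704 genes, 1044 were called, 559 positive and 485 negative. The genes named next leave out clone-type names. Fxyd4, a regulator of the sodium pump, had 9.14 ± 4.15 FPKM in EpiLC chromatin and 0.0148 ± 0.0256 in EpiLC cytoplasm, against 3.45 ± 1.26 and 3.37 ± 0.452 in nESC (SD, n = 3), a log2 value of 4.22 (SE 0.43, adjusted p = 6.83e-05). It was followed by the calcium-binding protein gene S100a1 at 3.23, mt-Co3 at 3.21 (SE 0.73, adjusted p = 0.0089), the aspartic protease gene Napsa at 3.17 and the retrieval receptor gene Kdelr3 at 3.13. Since mitochondrial messages are not made in the nucleus, values of mitochondrial genes are not read as a change of distribution. At the negative end stood Hsp90aa1 at -7.19 (SE 0.43, adjusted p = 3.29e-07) and the ribosomal RNA processing genes Rrp1 at -7.15, Rrp7a at -6.67, Rrp36 at -6.37 and Rrp15 at -6.05. Their nESC cytoplasm values were under 3 FPKM in every library, so these values are not read as a change of distribution.

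Formative and signalling genes included several with a larger cytoplasm share in EpiLC. The kinase gene Pim2 (ENSMUSG00000031155, chromosome X, 7878262 to 7883432) had 30.7 ± 4.3 FPKM in chromatin and 118 ± 25 in cytoplasm of EpiLC against 9.56 ± 0.528 and 2.86 ± 0.175 in nESC, a log2 value of -3.40 (SE 0.23, adjusted p = 1.13e-06). Dnmt3l was at -2.12 (SE 0.28, adjusted p = 0.000407), Dnmt3a at -1.49 and Dnmt3b at -1.41. Lin28b was positive at 1.8 (SE 0.39, adjusted p = 0.00654), a call lost with a pseudocount of 0.1 (0.98). Of 23 formative genes 3 were positive and 8 negative (median -0.51, camera adjusted p = 0.0843). Of 23 naive genes 3 were positive and 2 negative (0.32, adjusted p = 0.103), with Dppa3 at 2.10 and the imprinting factor gene Zfp57 at -1.77. MEK and GSK3 response genes were negative in 4 of 14 cases and positive in 0 (-0.43, 0.00525), with the ERK phosphatase gene Dusp6 at -1.58 and the Wnt target Axin2 at -1.23. Adjusted p was 0.338 with an estimated correlation. Pou5f1 at 0.51, Gapdh at 0.08 and Malat1 at -0.31 were not called (adjusted p = 0.157, 0.832 and 0.508). Apoe, the only primitive endoderm gene tested, was at 1.52.

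Replication histones were positive in 26 of 60 cases and negative in 0 (median 0.94, camera adjusted p = 7.06e-21), with Hist1h2ap at 2.07 and Hist3h2a at 1.93. Adjusted p was 0.338 with an estimated correlation. Genes with detained introns were negative in 17 of 41 cases (-0.77, 1.85e-14), with Hnrnpa2b1 at -1.57 and the splicing factor gene Srsf2 at -1.52. Chromatin regulators were negative in 7 of 51 (-0.39, 5.87e-06). Adjusted p was 0.338 and 0.338 in that order with an estimated correlation. Ribosomal protein genes had 7 of 78 positive and 1 negative, or 2 and 1 adjusted over the list alone (0.58, 1.1e-06), with Rpl12 at -4.69 (SE 0.24, adjusted p = 5.62e-08), Rps27 at 1.37, Rps10 at 1.33 and Rpl35 at 1.26. Adjusted p was 0.684 with an estimated correlation. Noncoding RNAs were negative in both lists, in 5 of 16 nuclear (-0.47, 0.00525) and 4 of 12 exported ones, where 1 was positive (-0.65, 0.00321), with Neat1 at -1.59, Meg3 at -1.04, Snhg5 at -1.54 and Gas5 at -1.49. Adjusted p was 0.338 and 0.338 in that order with an estimated correlation. The secretory pathway had 5 of 53 positive, or 4 adjusted over the list alone (0.36, 0.00617), with the cathepsin gene Ctsb at 1.86 and the Nodal inhibitor gene Lefty1 at 1.34. Immediate early genes had 6 of 21 positive and 1 negative (0.57, 0.00584), with Gadd45b at 1.54. Adjusted p was 0.715 and 0.338 in that order with an estimated correlation. The mitochondrial genome had 4 of 13 positive (0.70, adjusted p = 0.0843), with mt-Co1 at 2.07 (SE 0.65, adjusted p = 0.039), and Otx2 was at 1.05 (SE 0.30, adjusted p = 0.0254).

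Several of these calls ended when 1 library was left out, most of them with little change in the value. The call on Rps27 ended without nESC chromatin replicate 2 (1.34) or 3 (1.28), nESC cytoplasm replicate 1 (1.32) or 3 (1.33), EpiLC chromatin replicate 3 (0.97) and EpiLC cytoplasm replicate 1 (1.37) or 3 (1.28). The call on Otx2 ended without nESC chromatin replicate 1 (0.85) or 2 (0.93), nESC cytoplasm replicate 1 (1.04) or 3 (1.01), EpiLC chromatin replicate 2 (1.02) and EpiLC cytoplasm replicate 2 (1.01). The call on Meg3 ended without nESC chromatin replicate 3 (-0.98), nESC cytoplasm replicate 2 (-0.99), EpiLC chromatin replicate 3 (-0.99) and EpiLC cytoplasm replicate 3 (-0.88). The call on mt-Co1 ended without nESC chromatin replicates 1 to 3 (2.18, 2.21 and 1.81), nESC cytoplasm replicates 1 to 3 (2.24, 1.95 and 2.01) or EpiLC cytoplasm replicates 1 to 3 (2.13, 1.96 and 2.11). Without EpiLC chromatin replicate 3 it kept its call at 1.37, and mt-Co3 kept its call at 2.39. Without both EpiLC libraries numbered 3, 993 genes were called. Lefty1 (0.84), Rpl35 (1.00) and Rps27 (0.88) were no longer called. The secretory list (0.09, adjusted p = 0.346) and the nuclear noncoding list (-0.27, adjusted p = 0.055) no longer passed camera, and the respiratory chain list passed it at -0.28. Without the 36 genes whose cytoplasm to total ratio was far lower in nESC, 1018 genes were called. The median of all genes was -0.023, and -0.119 without centring (452 positive, 662 negative) and -0.215 after scaling to one sum (342 positive, 848 negative). With no filter 850 were positive and 1030 negative.

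**Figure D3:**
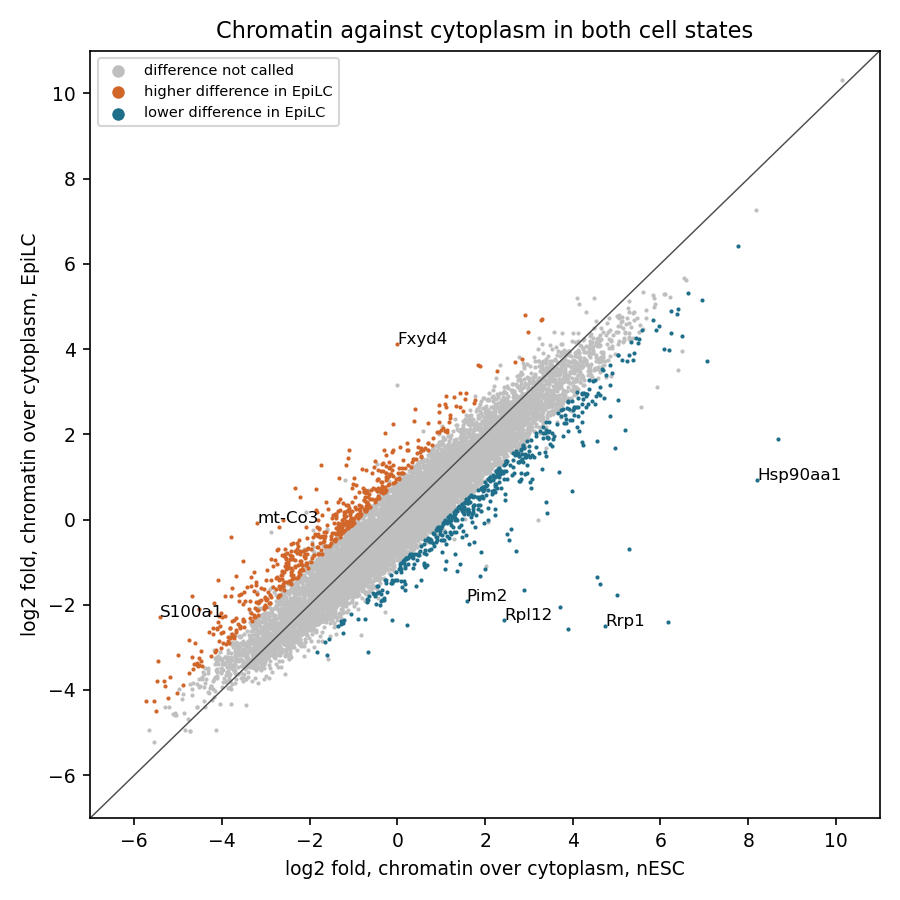
Log2 fold of chromatin over cytoplasm as deposited in nESC (x axis) and EpiLC (y axis), 1 point per gene for 11704 genes, with the 559 genes of a larger and the 485 of a smaller centred difference in EpiLC in colour and the line of equality. The folds of the states had an r of 0.941 and a slope of 0.847 (EpiLC on nESC), and Hsp90aa1, Rrp1 and Rpl12 lie far below the line.

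**Figure D4:**
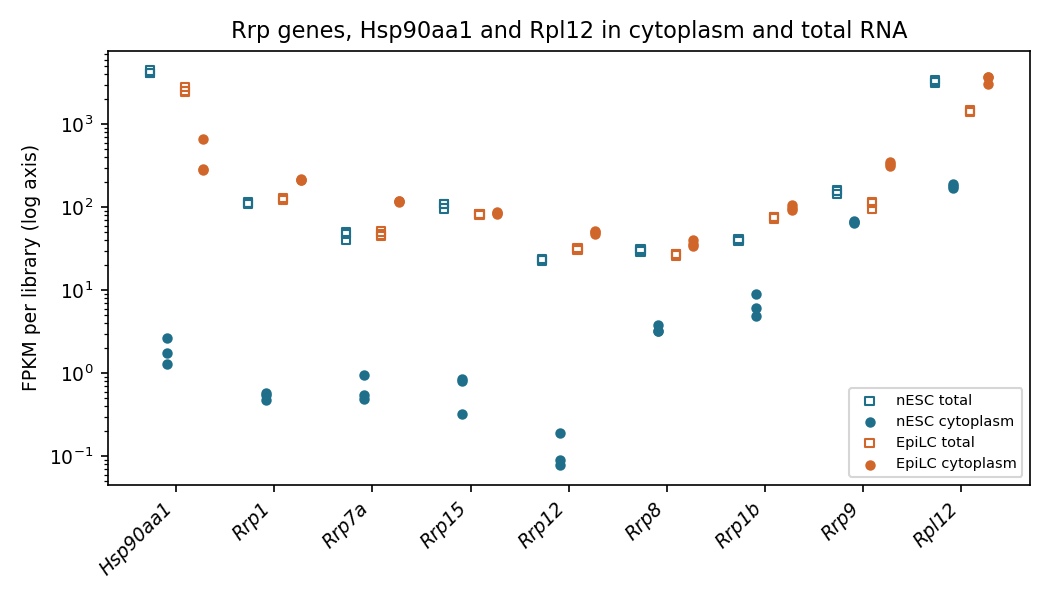
FPKM per library on a log axis (y axis) of 9 genes (x axis) in nESC and EpiLC, with filled points for cytoplasm and open points for total RNA. Hsp90aa1 stood at 1.31 to 2.63 in nESC cytoplasm and 281 to 676 in EpiLC cytoplasm and Rrp1 at 0.481 to 0.581 and 213 to 217, while both were above 100 in all 6 total libraries; Rrp12, Rrp8, Rrp1b and Rrp9 were chosen after their values were seen.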

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

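The tests on the EpiLC libraries numbered 3 and on the Rrp genes were chosen only after those patterns were seen.

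The interaction test called 1044 genes between nESC and EpiLC, which is what marked every result of this paragraph. Of these, 26 are among 36 genes far lower in nESC cytoplasm, whose values are treated in the last paragraph. Toward chromatin in EpiLC lay Fxyd4 at 4.22, S100a1 at 3.23, mt-Co3 at 3.21, Napsa at 3.17, Kdelr3 at 3.13, Dppa3 at 2.1, mt-Co1 at 2.07, the histone genes Hist1h2ap at 2.07 and Hist3h2a at 1.93, Ctsb at 1.86, Lin28b at 1.8, Gadd45b at 1.54, Apoe at 1.52, Rps27 at 1.37, Lefty1 at 1.34, Rps10 at 1.33, Rpl35 at 1.26 and Otx2 at 1.05. Since mitochondrial messages are not made in the nucleus, the values of mt-Co3 and mt-Co1 cannot be read as a shift to chromatin. Toward cytoplasm lay Hsp90aa1 at -7.19, Rrp1 at -7.15, Rrp7a at -6.67, Rrp36 at -6.37, Rrp15 at -6.05, Rpl12 at -4.69, Pim2 at -3.4, Dnmt3l at -2.12, Zfp57 at -1.77, Neat1 at -1.59, Dusp6 at -1.58, Hnrnpa2b1 at -1.57, Snhg5 at -1.54, Srsf2 at -1.52, Gas5 and Dnmt3a at -1.49, Dnmt3b at -1.41, Axin2 at -1.23 and Meg3 at -1.04. By list, the medians were 0.94 for replication histones, 0.58 for ribosomal proteins, 0.57 for immediate early genes, 0.36 for the secretory pathway, -0.77 for genes with detained introns, -0.65 for exported and -0.47 for nuclear noncoding RNAs, -0.43 for MEK and GSK3 response genes and -0.39 for chromatin regulators. None of these list calls held with an estimated correlation. Without both EpiLC libraries numbered 3 the secretory and nuclear noncoding lists no longer passed camera. All of these medians were opposite in sign to the list's median fold in nESC as deposited, though the secretory pathway had almost no fold there. A weaker separation of the fractions in EpiLC (slope of 0.847 across genes) cannot be told apart from shifts of these lists. The proteasome, housekeeping, long and zinc finger lists had no smaller medians in EpiLC.

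Splits of the libraries do not settle whether chance gives this count. Of 100 splits of chromatin and cytoplasm within the states, 7 gave as many called genes, the real one included, and the highest other gave 7345. Of 100 splits that exchanged the cell states within each fraction, 5 did, with 4487 as the highest other. All 6 other splits of the first set let the difference between the fractions itself into the contrast, with a weight of 1.33, and all 4 of the second set that between the states, with a weight of 1.33 to 2, where the real split has 0. They therefore measure a known structure of the samples. Of the splits with a weight of 0, 44 and 42 besides the real one, none gave as many, but their groups mix fractions or states, so that difference enters their spread and they do not decide it either. In simulated data of 11704 genes, changed ones included, 6 unchanged genes were called. Those data were independent normal values around 1 mean per gene, with no deviating libraries and no further difference between fractions or states. They do not decide it either.

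For the 8 comparisons of fractions, 10 splits of 6 libraries are too few for a share under 0.05. The real counts were 7745, 5028, 4374 and 4453 in nESC and 7386, 5035, 4199 and 3890 in EpiLC, in the order of the report, and only the real split, 1 of 10, reached each. The highest other split called 1 gene in the first pair of nESC comparisons and 0 genes in every other one.

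Messages of secreted and membrane proteins and of the mitochondrial genome were higher in nucleoplasm than in cytoplasm. Endoplasmic reticulum left with the nuclei would raise all genes whose protein starts with a hydrophobic stretch, and outside the secretory list such genes (1671 in nESC, 1742 in EpiLC) lay above other coding genes by 0.5 in nESC (95% bootstrap interval 0.43 to 0.56) and 0.47 in EpiLC (0.40 to 0.55), where the bound set beforehand was 0.5 in both, so the test leaves this explanation open. Transcript length and GC content as the whole cause would have brought the difference under 0.2, and after correction it was 0.6 in nESC and 0.54 in EpiLC. Export of the messages of secreted and membrane proteins at another rate was not tested. The test does not cover the mitochondrial messages, which are not made in the nucleus.

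EpiLC chromatin and cytoplasm libraries numbered 3 stood apart from their groups, with mt-Co3 at 11500 FPKM in chromatin replicate 3 against 2507 and 1875. RNA of other fractions mixed into both libraries may be the source, since their deviations from 1 library of the group correlated across genes with the distance of the other fractions from the remaining library, at r of 0.47 and 0.49 in chromatin and 0.54 and 0.56 in cytoplasm. Libraries 1 and 2, compared with one another, had -0.15 and 0.15 in chromatin and 0.03 and -0.03 in cytoplasm. By construction each pair is 1 value with its sign turned. The nESC libraries of these fractions had -0.26 to 0.26, mirrored in the same way. Hsp90b1 and Malat1 went with mixing in both libraries, but Gapdh in chromatin replicate 3 did not (998.6 FPKM against 963.3 and 1027). For mt-Co3, cytoplasm replicate 3 was the lowest (3620 against 4151 and 4248), although nucleoplasm held more of it. An exchange of labels is argued against by a mean correlation with the own fraction at least 0.219 above that with the opposite one. Lower depth of these libraries is argued against too, since only 1 of them had the fewest fragments of its group (37.3 behind 1 FPKM against 37.4 and 44.3), while chromatin replicate 3 had the most (48.0 against 31.2 and 40.1). A difference between cultures stays open and was not tested.

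Genes named Rrp and transcripts over ribosomal RNA repeats were lower against total RNA in nESC cytoplasm than in EpiLC cytoplasm. Rrp1 and Rrp15 were nearly absent there, while Rrp9 kept 65.5 to 69.5 FPKM. The repeat transcript Gm26917 was also at 0 in all 6 chromatin libraries of both states, which the counts below do not cover. A filter built on ribosomal RNA names or repeats that took reads out of these libraries stays open as a candidate explanation. All 11 such genes had a cytoplasm to total difference between the states under -2, against 25 of 10879 other genes (0.23%), but they were chosen because they showed the pattern, so this count does not test the filter. A lower cytoplasmic share of ribosome biogenesis messages in nESC, as the cause of differences under -2, is argued against by 34 Nop, Nol, Utp and Exosc genes. Their median was -0.54, and 1 of them was under -2. The 10879 other genes had a median of -0.15, so a smaller difference of this kind stays open. Among the 25 were Hsp90aa1 (-8.06), Exosc5 (-6.28), Rpl12 (-5.46), Cmtr1 (-5.44), Dis3 (-2.96) and Rrnad1 (-2.86), named after their values were seen. None of these has a symbol of the form Rrp and a number. Their other names and full names were not checked, so whether such a filter would reach them stays open. No step of this kind is recorded in the sources used here. Until it is settled, neither the interaction values of Rrp1, Rrp7a, Rrp36, Rrp15, Hsp90aa1 and Rpl12 nor any fold of these genes or of Gm26917 that involves nESC cytoplasm can be read as a distribution of RNA. The same holds for the folds of Gm26917 that involve chromatin.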

How the results depend on the processing

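Isolated zeros as missing, both EpiLC libraries numbered 3 left out, the length and GC correction and the sum scaling of lists were chosen only after the data were seen. Over all alternatives 157 counts of called genes stayed within 1.5 times and 6 did not. Of the values of named genes 4106 kept direction and side of the threshold, 74 lost the call, 6 gained one and 17 reversed. Of list results 1150 kept both, 136 lost the call, 26 gained one and 40 reversed, 105 of the losses with the estimated correlation. For the results listed here the cause was not tested, except that filters change how many genes are tested and that scaling moves all genes together.

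With the length and GC correction 3246 genes were called between nucleoplasm and cytoplasm and 2517 between cytoplasm and total in nESC, and 3174 and 2032 in EpiLC. For the interaction 1880 genes were called with no filter and 618 with a mean of at least 5 FPKM.

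Leaving out each library in turn gave 7654 to 7787 called genes for chromatin against cytoplasm, 4891 to 5160 for nucleoplasm against cytoplasm, 4365 to 4418 for chromatin against nucleoplasm and 4387 to 4576 for cytoplasm against total in nESC. In EpiLC the ranges were 7240 to 7581, 4768 to 5436, 4054 to 4554 and 3584 to 4412, and 933 to 1228 for the interaction.

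With the replicate number as a block the counts were 7748, 5028, 4376 and 4454 in nESC, 7386, 5033, 4200 and 3891 in EpiLC and 939 for the interaction. Deviations of libraries with the same number correlated at -0.13 to 0.15 in nESC and -0.22 to 0.18 in EpiLC. Such correlations between different fractions cannot show whether these libraries share a culture or a preparation. Under the block the formative list turned by camera in nESC chromatin against nucleoplasm (median -0.06, sign kept), as did the fibroblast list in EpiLC chromatin against cytoplasm (-0.28, sign kept), and Rps27 lost its interaction call.

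After scaling to one sum Nanog (0.03) and Sox2 (1.45) in nESC chromatin against cytoplasm, and Nanog (0.36), Sox2 (0.93), Otx2 (1.54), Fgf5 (0.78) and Dnmt3b (0.7) in EpiLC, reversed, as did Gapdh in the interaction (-0.15). Lists that reversed in the median or by camera were, in nESC, the mitochondrial genome (2.51) and naive genes (1.71) for chromatin against cytoplasm, MEK and GSK3 response (0.7) and clone-named genes (0.86) for nucleoplasm against cytoplasm, formative genes (0.64) for chromatin against nucleoplasm, and proteasome (-0.63) and naive genes (-0.75) for cytoplasm against total. In EpiLC they were core (1.48), MEK and GSK3 response (1.58) and fibroblast genes (1.46), clone-named genes (0.55), chromatin regulators (0.75), and immediate early (-0.6) and MEK and GSK3 response genes (-0.7) in the same order of comparisons, and clone-named genes (-0.15) in the interaction.

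With the length and GC correction Kcnq1ot1 (-0.76) and Sox2 (0.07) in nESC and Neat1 (-0.47) in EpiLC reversed for chromatin against cytoplasm, and Tug1 (-0.12) for EpiLC nucleoplasm against cytoplasm. Lists were, in nESC, the mitochondrial genome (-1.28) and immediate early genes (-0.33) for chromatin against cytoplasm, immediate early (-0.01), MEK and GSK3 response (-0.05) and 2-cell-like genes (-0.55) for nucleoplasm against cytoplasm, and the mitochondrial genome (0.97), long (0.58) and formative genes (0.08) for cytoplasm against total. In EpiLC they were the mitochondrial genome (-0.47) and naive genes (-0.21), nuclear noncoding RNAs (-0.47) and immediate early genes (0.08), and immediate early (-0.16), formative (0.0) and MEK and GSK3 response genes (0.09).

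Centring turned core genes (-0.15) in nESC chromatin against cytoplasm and naive (-0.21) and formative genes (-0.22) in nESC nucleoplasm against cytoplasm. A pseudocount of 0.1 turned formative genes in nESC chromatin against nucleoplasm by camera (-0.06, sign kept), and one of 1 turned clone-named genes in the interaction (-0.01, sign kept). Without both EpiLC libraries numbered 3, chromatin regulators (0.09) in EpiLC chromatin against nucleoplasm and the respiratory chain (-0.28), clone-named genes (-0.01) and Malat1 (0.1) in the interaction reversed. Gapdh in the interaction lay at -0.04 with no filter, -0.02 without centring, -0.02 without both libraries numbered 3 and from 0.0 (without EpiLC cytoplasm replicate 3) to 0.17 with single libraries left out. Depth limits low genes most in chromatin and cytoplasm, with 24.2 to 48.0 fragments behind 1 FPKM in 2 kb.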

Other observations

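By gene class, long noncoding genes lay toward chromatin and pseudogenes toward cytoplasm. In nESC 617 of 958 long noncoding genes were called higher in chromatin than in cytoplasm and 141 lower, with a median log2 fold of 1.81, and in EpiLC 644 of 964 were higher and 89 lower, with the same median. Coding genes had medians of -0.06 and -0.10. Pseudogenes, which share reads with near-identical parents, had -1.97 over 45 genes and -1.75 over 40 genes. Between nucleoplasm and cytoplasm the long noncoding medians were 0.17 in nESC and -0.07 in EpiLC. Exonic length went with the chromatin to cytoplasm fold across coding genes, which are not independent replicates, at a Spearman's rho of 0.57 in nESC and 0.56 in EpiLC, and GC content at -0.39 and -0.38. The median fold of the shortest and the longest quintile of coding genes was -1.83 and 1.46 in nESC and -1.69 and 1.23 in EpiLC.

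The immediate early genes Fos and Fosb differed between total RNA and the fractions. In nESC Fos had 46.9 ± 4.88 FPKM (SD, n = 3) in chromatin, 9.07 ± 0.974 in nucleoplasm and 2.72 ± 0.203 in cytoplasm against 0.782 ± 0.674 in total RNA, while in EpiLC it had 23.4 ± 0.602, 2.69 ± 1.03 and 2.34 ± 0.777 against 36.4 ± 2.7. Fosb had 7.58 ± 0.702 in nESC chromatin and 0.205 ± 0.14 in total RNA, and 20.3 ± 5.98 and 19.5 ± 0.641 in EpiLC. Egr1 had 4.42 ± 1.51 in EpiLC chromatin and 11.2 ± 0.929 in total RNA. Malat1 was listed at 0 in nESC nucleoplasm replicate 3.

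Before the result was seen, it was asked whether messages with a higher level in EpiLC shift toward the cytoplasm there. Across 11704 genes Spearman's rho between the level difference in total RNA and the interaction value was -0.13, between the bounds of -0.2 and -0.1 set for the test, so the test leaves it open.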
